A study of Mus musculus with 18 samples.

How the data were processed

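The samples were 18 RNA-seq libraries of CD8 T cells sorted from mouse spleen, 6 for each of 3 diets: normal diet for 12 weeks (ND), high fat diet for 12 weeks (HFD), and a switched diet (SW), in which 6 weeks of high fat diet were followed by 6 weeks of normal diet. Per the labels' protocols, RNA was taken from freshly isolated cells with a spin column kit, messenger RNA was selected by poly-T beads, and complementary DNA was primed with random hexamers. The labels do not say whether strand was kept, so reads of a gene and of a gene antisense to it cannot be told apart. CD4 T cells and B cells, which the design text also mentions, were not analysed here.

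Per the submitters' processing notes, reads were processed with fastp and the genome builds GRCm38 and mm10 were used. The aligner, the counting tool and the annotation are not given in the sources used here. The authors deposited a file of raw counts per gene for each library, with no normalization. They also deposited a file of FPKM values for each library. The deposited FPKM values were checked for the 9534 genes with a count above 50 in every library. Each equalled the count times a factor of the gene and a factor of the library, with a largest relative departure of 4.76e-09. The count files hold 56748 Ensembl gene IDs, of which 52073 matched GENCODE M21 (GRCm38) and 4675 did not. Symbols and coordinates are from GENCODE M21, whose release may differ from the one the authors used.

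Total counts ran from 11947339 to 16398340 per library. They averaged 13894300 ± 1868970 (SD, n = 6) in ND, 13633600 ± 1116860 in SW and 14740000 ± 1209810 in HFD. PCR copies were not marked, so counting error is a lower limit of the error.

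Counts were tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3), with TMM normalization, the filterByExpr filter on low counts and a robust fit. All 18 libraries entered 1 fit with diet as the only factor, and 13690 genes passed the filter, 232 of them without a symbol. The common biological coefficient of variation was 0.115. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Adjusted p-values given for genes are from this test unless another is named. Fold changes are on the log2 scale with the standard error (SE) of the fit, and levels are normalised counts scaled by library size (CPM, as edgeR computes them) with the SD over 6 libraries. The number of libraries in the direction of a difference counts libraries of the diet named first that lie beyond the mean of the other diet. The labels do not say that the libraries of a diet came from separate mice, so the p-values measure the spread between samples, which may be technical in part.

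The comparisons were HFD against ND, SW against ND, SW against HFD, and any difference among the 3 diets. The comparisons, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where said. The rule took the 8 genes with the largest positive and the 8 with the largest negative fold change among called genes of at least 1 CPM, leaving out unnamed gene models and antigen receptor segments. It added up to 4 members of each gene list by smallest p, genes called with the same sign in HFD and in SW against ND, and a fixed set with Gpx4, Acsl4, Tfrc, Fth1, Ftl1, Cd8a, Cd8b1, Cd44 and Gzmb. Slc7a11 and Aifm2, also in that set, did not pass the filter on low counts, and 1 further gene of the set is not reported here. Some of the genes taken by the rule are given only in counts.

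A total of 32 gene lists covered pathways, CD8 T cell states, RNA quality and markers of other cells of the spleen. The 29 lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. Within a list, p-values were also adjusted over the list alone.

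The steps were tested on simulated data with known changes. Of 50 genes changed by 1.25-fold in simulated libraries for HFD against ND, edgeR recovered 26%, and it recovered 70% at 1.5-fold, 84% at 2-fold and 94% at 3-fold, out of 13541 genes. For SW against ND the shares were 34%, 66%, 86% and 92% of 13547 genes. For SW against HFD they were 42%, 72%, 86% and 94% of 13532 genes. Unchanged genes made up 6.16%, 7.95% and 4.55% of the calls in the respective simulations.

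The alternatives were DESeq2 1.42.0, limma-voom with sample weights, limma on log2 FPKM with an added 0.1 or 1, other size factors, other filters on low counts, the replicate number as a block, replicates 1 to 3 against 4 to 6 as a factor, fits of only the diets compared, a fit without receptor, haemoglobin and mitochondrial genes, and leaving out each library in turn. Further alternatives, chosen after the data were seen, used replicates 1 and 2 against 3 to 6 as a factor, only 1 of these sets, all libraries but HFD 1 and HFD 4, or the level of dendritic cell or erythroid markers as a covariate. The figures were drawn with matplotlib 3.10.9.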

Results

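Gene expression was measured by poly-A RNA-seq in CD8 T cells sorted from the spleens of mice on 3 diets, with 6 libraries per diet. ND mice were kept on normal diet and HFD mice on high fat diet, each over 12 weeks. SW mice were moved from high fat to normal diet after 6 weeks and were kept on it for the other 6. Total counts per library lay between 11947339 and 16398340, and the 10 most abundant genes held 5.70% to 6.96% of the counts. Cd8a and Cd8b1, which encode the chains of the CD8 co-receptor, had like levels on all diets, with Cd8a at 1490 ± 64.1 CPM (SD, n = 6) in ND, 1520 ± 64.9 in SW and 1480 ± 76.6 in HFD. The first principal component of the expression values, with 21.2% of the variance, parted replicates 1 and 2 of every diet, at -7.69 or lower, from replicates 3 to 6, at -3.53 or higher. The labels do not say what the replicate numbers mark, and each diet has 2 libraries on the low side and 4 on the high side. On the second component, with 13.8% of the variance, all ND libraries lay at 3.32 or higher and all HFD libraries at -3.26 or lower. The SW libraries ran from -3.98 to 5.18 on it.

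HFD was compared with ND to ask what a continued high fat diet changes in these cells. In the edgeR test 8 of 36 genes of effector and memory CD8 T cells rose. The linker histone genes Hist1h1e and Hist1h1c, of a list fixed for RNA quality, rose as well, and Tnf and 4 of 34 type I interferon response genes fell. The interferon list was lower in camera but not with an estimated correlation (adjusted p = 0.213). The edgeR quasi-likelihood test called 222 of 13690 genes, 91 higher and 131 lower in HFD, and 2038 genes had an unadjusted p under 0.05. The median size of the called changes was 0.36 on the log2 scale, and 47 of the 222 changed by at least 1.5-fold. The counts without 1 library ran from 89 to 301, the highest without HFD 1, and they were 151 to 247 in the fits without ND 1, ND 2, HFD 3, HFD 5 or an SW library. The count was 109 without ND 3, 130 without ND 4, 89 without ND 5, 132 without ND 6, 127 without HFD 2, 145 without HFD 4 and 117 without HFD 6. Within replicates 3 to 6 alone 201 genes were called, and 127 of them were among the 222. Within replicates 1 and 2 alone, with 2 libraries per diet, 5 were called, and with the 2 sets of replicates as a factor 535 were called, 221 of them among the 222. A fit without HFD 1 and HFD 4 called 230 genes, of which 141 were among the 222.

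Among the named genes that rose, Hist1h1e (ENSMUSG00000051627; 13, 23620629 to 23622558, GRCm38), a linker histone gene, had the largest change, at 2.03 ± 0.36 (SE; adjusted p = 0.00501), from 0.495 ± 0.154 CPM in ND to 2.04 ± 0.426 in HFD (SD, n = 6), in 6 of 6 libraries. Ctla4 (ENSMUSG00000026011; 1, 60887000 to 60915832), an inhibitory receptor of T cells, rose by 1.44 ± 0.34 (adjusted p = 0.0428), from 4.36 ± 0.894 to 11.9 ± 7.02 CPM, in 5 of 6 libraries. Cx3cr1 (ENSMUSG00000052336; 9, 119901616 to 120069879), a chemokine receptor of differentiated effector cells, rose by 1.26 ± 0.31 (adjusted p = 0.0455), from 4.87 ± 2.62 to 11.5 ± 3.42 CPM. Plxnb2, a semaphorin receptor gene, rose by 1.22 ± 0.26 (adjusted p = 0.0173), Sirpa by 1.15 ± 0.29, Smpdl3b by 1.09 ± 0.25, the integrin gene Itga1 by 1.07 ± 0.28 and the palmitoyltransferase gene Zdhhc2 by 1.05 ± 0.19 (adjusted p = 0.00561). Of these 8 genes, Hist1h1e, Plxnb2 and Zdhhc2 were called in all 18 fits without 1 library. Ctla4 was called in 5 of them, Cx3cr1 in 4, Itga1 in 3, Sirpa in 7 and Smpdl3b in 9, with adjusted p up to 0.0973, 0.107, 0.113, 0.0924 and 0.0746.

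Among the named genes that fell, Klf10 (ENSMUSG00000037465; 15, 38291463 to 38300706), a TGF-beta-inducible transcription factor, changed by -0.91 ± 0.17 (SE; adjusted p = 0.00675). The polycomb gene Cbx8 changed by -0.81 ± 0.12 (adjusted p = 0.00193), from 25.9 ± 2.79 CPM in ND to 14.8 ± 3.46 in HFD (SD, n = 6). The non-coding transcript Gt(ROSA)26Sor changed by -0.80 ± 0.13, Mex3b, which encodes an RNA-binding protein, by -0.80 ± 0.16, Nradd by -0.79 ± 0.13, Csrnp2 by -0.79 ± 0.12 and G0s2 by -0.76 ± 0.17. Tnf (ENSMUSG00000024401; 17, 35199381 to 35202007), an inflammatory cytokine, changed by -0.75 ± 0.16 (adjusted p = 0.0173), from 19.1 ± 4.85 to 11.4 ± 2.41 CPM, in 6 of 6 libraries. All 8 but G0s2, which was called in 11 of the 18 fits without 1 library (adjusted p up to 0.0686), were called in every such fit.

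Of 36 tested genes of the effector and memory list, 8 rose and 0 fell in HFD in the edgeR test, against 17 and 0 when adjusted over the list alone. The 8 were Id2, Cd44, Itgb1, Prdm1, Ccl5, Zeb2, Fasl and Cx3cr1. Cd44 (ENSMUSG00000005087; 2, 102811141 to 102901665), an adhesion receptor of antigen-experienced T cells, rose by 0.36 ± 0.07 (SE; adjusted p = 0.00561), from 61.6 ± 4.47 to 79.0 ± 6.26 CPM (SD, n = 6). Itgb1, an integrin chain, rose by 0.49 ± 0.09 (adjusted p = 0.00969), from 171 ± 12.3 to 239.9 ± 35.4 CPM. Prdm1, a transcription factor of terminal effector cells, rose by 0.91 ± 0.19 and Ccl5, a chemokine, by 0.56 ± 0.13. Gzmb, which encodes granzyme B, was not called, at 1.57 ± 0.42 (adjusted p = 0.0711). The list median was 0.36, with 33 of 36 members above 0, and the list passed camera (adjusted p = 8.87e-16; adjusted p = 0.0454 with an estimated correlation). In the fits without 1 library, Cx3cr1, Fasl, Ccl5 and Zeb2 were called in 4, 5, 9 and 10 of 18, and the other 4 in all 18.

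Of 20 tested genes of naive and central T cells, Il7r rose and Id3 fell in HFD, and 4 rose and 3 fell when adjusted over the list alone. Il7r, the receptor chain for interleukin 7, changed by 0.43 ± 0.09 (SE; adjusted p = 0.0173), from 589 ± 43.3 to 795 ± 134 CPM (SD, n = 6), and Id3, a transcriptional regulator of naive and memory T cells, by -0.50 ± 0.10 (adjusted p = 0.00997). The list did not pass camera (median 0.06, adjusted p = 0.201). Of 14 genes of the inhibitory receptor list Ctla4 alone rose, with 4 higher when adjusted over the list alone. That list had a median of 0.39 (camera adjusted p = 0.000379; adjusted p = 0.134 with an estimated correlation).

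Of 34 tested type I interferon response genes, 4 fell and 0 rose in HFD, against 8 and 0 when adjusted over the list alone. Rtp4 (ENSMUSG00000033355; 16, 23520291 to 23614222), an interferon-induced gene, changed by -0.50 ± 0.09 (SE; adjusted p = 0.00354), from 62.7 ± 8.45 to 44.4 ± 5.40 CPM (SD, n = 6). Irf9, which encodes a subunit of the interferon-activated complex ISGF3, changed by -0.25 ± 0.05, the transcription factor Irf7 by -0.32 ± 0.08 and Ifit1 by -0.66 ± 0.15 (adjusted p = 0.0381). Rtp4 and Irf9 were called in all 18 fits without 1 library, Ifit1 in 10 and Irf7 in 9. The list median was -0.21, with 1 of 34 members above 0 (camera adjusted p = 1.24e-11; adjusted p = 0.213 with an estimated correlation). Without ND 6, whose interferon genes were the highest of the ND libraries, the median was -0.13 (camera adjusted p = 2.60e-07).

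Of 12 tested replication-dependent histone genes, whose messenger RNAs mostly lack a poly-A tail, Hist1h1e, Hist1h1c and Hist1h4n rose in HFD, and 5 were higher when adjusted over the list alone. These genes were fixed as the list on RNA quality. The list median was 0.53 (camera adjusted p = 2.30e-05; adjusted p = 0.00484 with an estimated correlation). Hist1h1c rose by 0.81 ± 0.16 (SE; adjusted p = 0.00997), and Hist1h4n, whose reads can be shared with near-identical histone genes, by 1.94 ± 0.42 (adjusted p = 0.0179), all at low levels, with a summed level of the list of 38.1 ± 3.46 CPM (SD, n = 6) in ND and 49.96 ± 3.60 in HFD. None of 30 proliferation genes was called, and that list had a median of 0.26 (camera adjusted p = 0.000143; adjusted p = 0.498 with an estimated correlation); without HFD 1 its camera adjusted p was 0.0523. None of 24 cholesterol synthesis genes was called, at a median of -0.17 (camera adjusted p = 0.0336; adjusted p = 0.661 with an estimated correlation), and that call was lost without ND 1, ND 5, HFD 2, HFD 5 or HFD 6, with adjusted p from 0.0837 to 0.231. None of 13 heat shock genes was called, and their median of -0.21 and mean of 0.29 differed in sign (camera adjusted p = 0.0150, lower; adjusted p = 0.661 with an estimated correlation; 0.150 without HFD 3).

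Genes that act for or against ferroptosis, an iron-dependent death by lipid peroxidation that the series title names, showed no called change in HFD. None of 22 tested genes of ferroptosis defence (median 0.03), 19 of ferroptosis promotion (median -0.05) and 17 of iron handling (median -0.01) passed the edgeR test over all genes or when adjusted over the list alone, and none of these lists passed camera (adjusted p = 0.476, 0.844 and 0.534). Gpx4 (ENSMUSG00000075706; 10, 80047166 to 80056439), which reduces lipid peroxides, had a fold change of -0.01 ± 0.05 (SE), with 98.6 ± 6.56 CPM in ND and 98.1 ± 7.35 in HFD (SD, n = 6). Acsl4, which activates polyunsaturated fatty acids, was at -0.08 ± 0.07, the transferrin receptor Tfrc at -0.15 ± 0.07, and the ferritin chains Fth1 and Ftl1 at 0.07 ± 0.06 and 0.00 ± 0.07. Of fat metabolism genes, Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, was at 0.66 ± 0.19 (adjusted p = 0.101), Cd36 at 0.68 ± 0.27 (adjusted p = 0.227) and Acsl3 at -0.62 ± 0.18 (adjusted p = 0.0699). Cd36 stood apart in HFD 1, at 4.05 log2 CPM, with the next HFD library at 3.02. None of 23 tested genes of fatty acid oxidation was called (median 0.07, camera adjusted p = 0.108), and fry gave that list an adjusted p of 0.0208.

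Markers of other cells differed between HFD and ND beside these groups. Of 9 B cell genes Ighm rose, by 0.24 ± 0.06 (SE; adjusted p = 0.0361), with a list median of 0.29 (camera adjusted p = 0.00665; adjusted p = 0.0454 with an estimated correlation), and it was called in 9 of 18 fits without 1 library. Of 11 monocyte, macrophage and neutrophil genes 0 were called by edgeR and 2 when adjusted over the list alone, at a median of 0.80 (camera adjusted p = 3.43e-05; adjusted p = 0.0454 with an estimated correlation), and their summed level was 116 ± 39.98 CPM in ND and 167 ± 56.1 in HFD (SD, n = 6). Of 4 plasma cell genes, too few for camera, Prdm1, which is also in the effector list, rose, and 2 were higher when adjusted over the list alone, at a median of 1.04. Of 9 erythroid genes 0 were called, and 6 were higher and 1 lower when adjusted over the list alone, at a median of 1.86 (camera adjusted p = 0.00240; adjusted p = 0.442 with an estimated correlation). Hba-a1, a haemoglobin gene with a near-identical copy, had 10.9 ± 3.33 CPM in ND and 44.7 ± 44.1 in HFD. With the erythroid marker level as a covariate, an alternative chosen after the data were seen, 80 genes were called, 68 of them among the 222. The lists of CD4 T cells (median 0.15), natural killer cells (0.20), gamma delta T cells (0.05), dendritic cells (0.24) and CD8 T cell identity (0.05) did not pass camera. Of these, the CD4 T cell list alone passed fry (adjusted p = 0.0184, higher), with 7 of 9 members above 0. In that list 0 genes were called by edgeR over all genes, and 2 were higher when adjusted over the list alone.

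**Figure D1:**
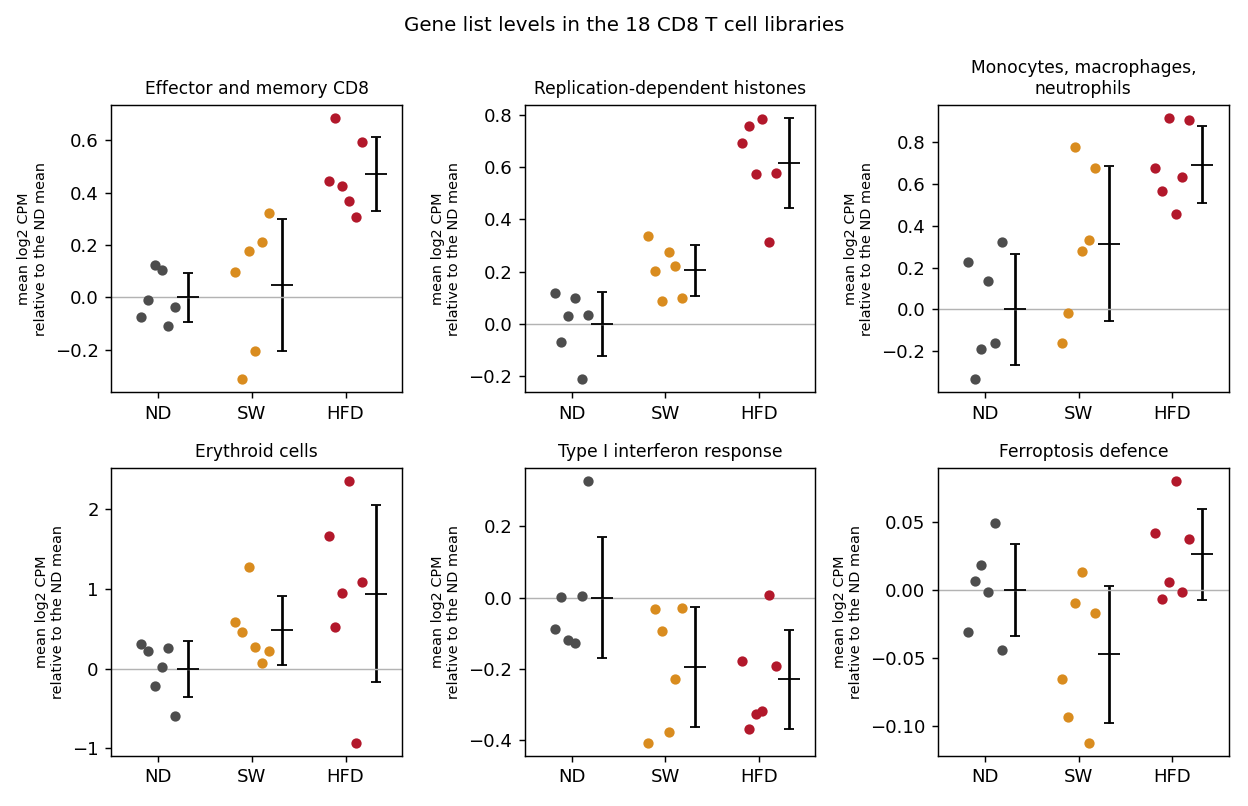
Mean log2 CPM of the genes of 6 lists in each library (vertical axis, relative to the ND mean of the list), by diet, with a point per library and the mean and SD of the 6 libraries beside them. Before the ND mean was taken off, the effector and memory list averaged 5.39 in HFD, 4.97 in SW and 4.92 in ND, and the interferon list 5.34, 5.37 and 5.57.

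SW was compared with ND to ask what differs after 6 weeks of high fat diet and 6 weeks back on normal diet. No group was sampled after the first 6 weeks. A change that reverted therefore cannot be told from one that had not yet arisen. The edgeR test called 2 genes, and 932 had an unadjusted p under 0.05. Tnf fell by 0.91 on the log2 scale (SE 0.16; adjusted p = 0.0481), from 19.1 ± 4.85 CPM in ND to 10.1 ± 1.62 in SW (SD, n = 6), in 6 of 6 libraries. It was the only gene called in both HFD and SW against ND. The non-coding gene 2010016I18Rik (ENSMUSG00000091575; 3, 106481982 to 106485913) rose by 0.61 ± 0.09 (adjusted p = 0.0195), from 82.7 ± 9.41 to 126 ± 21.04 CPM. Of the 18 fits without 1 library, 9 called Tnf (adjusted p up to 0.152) and 14 called 2010016I18Rik (adjusted p up to 0.0960). DESeq2 called 61 genes and limma-voom 29. With replicates 1 and 2 against 3 to 6 as a factor 22 were called, including both genes, against 5 within replicates 3 to 6, which included neither, and 0 within replicates 1 and 2, where edgeR gave 664 an unadjusted p under 0.05.

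Genes that had risen or fallen in HFD were measured in SW. Of the effector genes, Cd44 was at 0.07 ± 0.07 (SE) and Itgb1 at 0.09 ± 0.09 in SW against ND, and none of the 36 effector and memory genes was called over all genes or when adjusted over the list alone (median 0.03, camera adjusted p = 0.387). Mex3b, at -0.86 ± 0.16 (adjusted p = 0.0704), and Id3, at -0.41 ± 0.10 (adjusted p = 0.133), had values in SW like those in HFD but did not pass. The interferon list was lower in SW too, at a median of -0.17 with 2 of 34 members above 0 (camera adjusted p = 2.07e-11; adjusted p = 0.279 with an estimated correlation), with 0 genes called and 4 lower when adjusted over the list alone. Its median was -0.10 without ND 6 (camera adjusted p = 7.75e-05). Rtp4 was at -0.34 ± 0.08 and Ifit1 at -0.55 ± 0.15 in SW. Gpx4 was at -0.06 ± 0.05 with 94.6 ± 3.44 CPM in SW (SD, n = 6), Acsl4 at -0.02 ± 0.07, Tfrc at -0.13 ± 0.07, Fth1 at -0.03 ± 0.06 and Ftl1 at -0.03 ± 0.07, and the lists of ferroptosis defence (median -0.04), ferroptosis promotion (-0.02) and iron handling (-0.03) did not pass camera and held no called gene over all genes or when adjusted over the list alone.

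Besides the interferon list, 6 lists passed camera in SW against ND, all lower. None of the 7 passed with an estimated correlation or fry. The heat shock list had a median of -0.27 (adjusted p = 1.53e-06; adjusted p = 0.279 with an estimated correlation), with Dnajb1, a co-chaperone gene, at -0.56 ± 0.15 (SE; edgeR adjusted p = 0.304). Immediate early genes had a median of -0.08 (adjusted p = 0.000936; adjusted p = 0.595 with an estimated correlation), glycolysis genes -0.07 (adjusted p = 0.00402; adjusted p = 0.279 with an estimated correlation) and unfolded protein response genes -0.05 (adjusted p = 0.0242; adjusted p = 0.279 with an estimated correlation). Ribosomal protein genes had a median of -0.04 (adjusted p = 0.000527; adjusted p = 0.709 with an estimated correlation) and nuclear genes of oxidative phosphorylation -0.02 (adjusted p = 0.0414; adjusted p = 0.709 with an estimated correlation). None of the genes in these 6 lists was called by edgeR over all genes, and 1 each in the immediate early, heat shock and unfolded protein lists was lower when adjusted over the list alone.

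SW was compared with HFD to test directly whether the return to normal diet made a difference. The edgeR test called 17 genes, 8 higher and 9 lower in SW, and 1515 had an unadjusted p under 0.05. Fam129b (ENSMUSG00000026796; 2, 32876114 to 32925254) changed by -1.68 ± 0.29 (SE; adjusted p = 0.0251), from 1.85 ± 0.360 CPM in HFD to 0.570 ± 0.189 in SW (SD, n = 6), in 6 of 6 libraries, and Ncald, a calcium sensor gene, by -1.02 ± 0.20 (adjusted p = 0.0394). Fbxw8 and Phf13 each changed by -0.51, Dclre1b by -0.47, Odc1, the first enzyme of polyamine synthesis, by -0.32 and Nptn by -0.29, and below 1 CPM on average Hist1h4n changed by -2.07 and Car5b by -2.69. Gt(ROSA)26Sor rose by 0.64 ± 0.13 (adjusted p = 0.0394), from 13.3 ± 1.66 to 20.9 ± 4.76 CPM, and Clk1, a kinase of splicing factors, by 0.34 ± 0.07 (adjusted p = 0.0394). Alg2 rose by 0.44, Zfp707 by 0.42, Zfp738 by 0.36, Polr3f by 0.28 and AI504432 by 0.26. None of the 17 was called in all 18 fits without 1 library, and those fits called 0 to 44 genes. DESeq2 called 112 genes, limma-voom 8 and limma on log2 FPKM 0. In edgeR 116 were called with replicates 1 and 2 against 3 to 6 as a factor, 138 with the replicate number as a block, and 0 in a fit of only these 2 diets, where 1271 had an unadjusted p under 0.05, or with the dendritic cell marker level as a covariate, where 1383 did. With library totals in place of TMM 24 were called, 16 higher and 8 lower.

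The effector and memory list was lower in SW than in HFD, at a median of -0.34 with 2 of 36 members above 0 (camera adjusted p = 2.55e-16; adjusted p = 0.0443 with an estimated correlation). No member was called by edgeR over all genes, and 15 were lower when adjusted over the list alone. Cd44 was at -0.29 ± 0.07 (SE; adjusted p = 0.0711), Itgb1 at -0.40 ± 0.09 (adjusted p = 0.0807) and Prdm1 at -0.75 ± 0.19 (adjusted p = 0.107). The histone list was lower as well (median -0.28, camera adjusted p = 0.00396; adjusted p = 0.0443 with an estimated correlation), with Hist1h4n called and 3 lower when adjusted over the list alone. The interferon list did not differ in camera between SW and HFD (median 0.04, adjusted p = 0.118), and a camera p above the threshold does not show that the levels were equal.

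A further 10 lists were lower in SW than in HFD in camera and were not called with an estimated correlation. Proliferation genes had a median of -0.33 (camera adjusted p = 1.98e-09; adjusted p = 0.186 with an estimated correlation), with 0 called and 5 lower when adjusted over the list alone. The monocyte, macrophage and neutrophil list (median -0.37; adjusted p = 0.162 with an estimated correlation), inhibitory receptors (-0.31; adjusted p = 0.202 with an estimated correlation) and immediate early genes (-0.22; adjusted p = 0.323 with an estimated correlation) followed. Inflammatory genes (-0.09; adjusted p = 0.291 with an estimated correlation), glycolysis (-0.09; adjusted p = 0.185 with an estimated correlation), fatty acid oxidation (-0.09; adjusted p = 0.0564 with an estimated correlation) and unfolded protein response genes (-0.08; adjusted p = 0.186 with an estimated correlation) had smaller medians. Genes of the ferroptosis defence list had a median of -0.04 (camera adjusted p = 0.0170, and 0.202 with an estimated correlation). Of its 22 genes 0 were called over all genes or when adjusted over the list alone. Its camera call was lost without SW 2, SW 5 or HFD 4 (adjusted p = 0.0615, 0.0718 and 0.0992), and fry gave it an adjusted p of 0.0417, lower. By fry the lists of fatty acid oxidation (adjusted p = 0.00763), glycolysis (0.0189), unfolded protein response (0.0417) and monocytes, macrophages and neutrophils (0.0417) were lower too. Ribosomal protein genes had a median of -0.03 (adjusted p = 0.766 with an estimated correlation). Gpx4 was at -0.05 ± 0.05 (SE; edgeR adjusted p = 0.770).

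Over the 3 diets together, the edgeR test called 123 genes, and 1825 had an unadjusted p under 0.05. Of the 222 genes called in HFD against ND, 203 had the same sign in SW against ND. Both comparisons use the same ND libraries, and in 20 simulations without any diet effect 207 of the top 222 had the same sign on average, with a range of 200 to 212. The covariance of the fold changes of HFD and of SW against ND across the tested genes, which are not independent replicates, was 0.0266, against 0.0197 in the simulations (range 0.0183 to 0.0217), a difference of 0.00689. The observed value lay above all 20 simulations, and its jackknife SE over libraries was 0.0109, larger than the difference. The correlation was 0.474, against 0.499 in the simulations. With ND divided into 3 and 3 libraries, so that the comparisons share none and chance alone gives a value near 0, the covariance was 0.0138 on average over 20 divisions, with a range of 0.00365 to 0.0201. In the 12 divisions that part replicates 1 and 2 of ND it was 0.0153, with a range of 0.0121 to 0.0201. Over the 20 divisions, 173 of the top 222 genes had the same sign on average, with a range of 136 to 188. Independent lists of these sizes would share 0.00957 lower and 0.00665 higher genes between HFD and SW against ND, and 1 lower and 0 higher were shared. HFD against ND and SW against HFD rest on the same HFD libraries and shared 10 called genes, 5 lower and 5 higher in HFD than in both other diets. Simulations without any diet effect called 0.050 genes per comparison on average and shared 0. With so few calls they give no reference for the 10. Independent lists of the real sizes, which leave out the shared libraries, would share 0.0766 lower and 0.0598 higher genes. With HFD divided into 3 and 3 libraries, 0.15 genes were shared on average over 20 divisions, with a range of 0 to 1 and fewer libraries behind each fold change. The covariance of the fold changes of HFD against ND and of HFD against SW was 0.0434, against 0.0196 (range 0.0184 to 0.0222) in the simulations, and 0.0187 (range 0.0104 to 0.0254) with HFD divided.

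**Figure D2:**
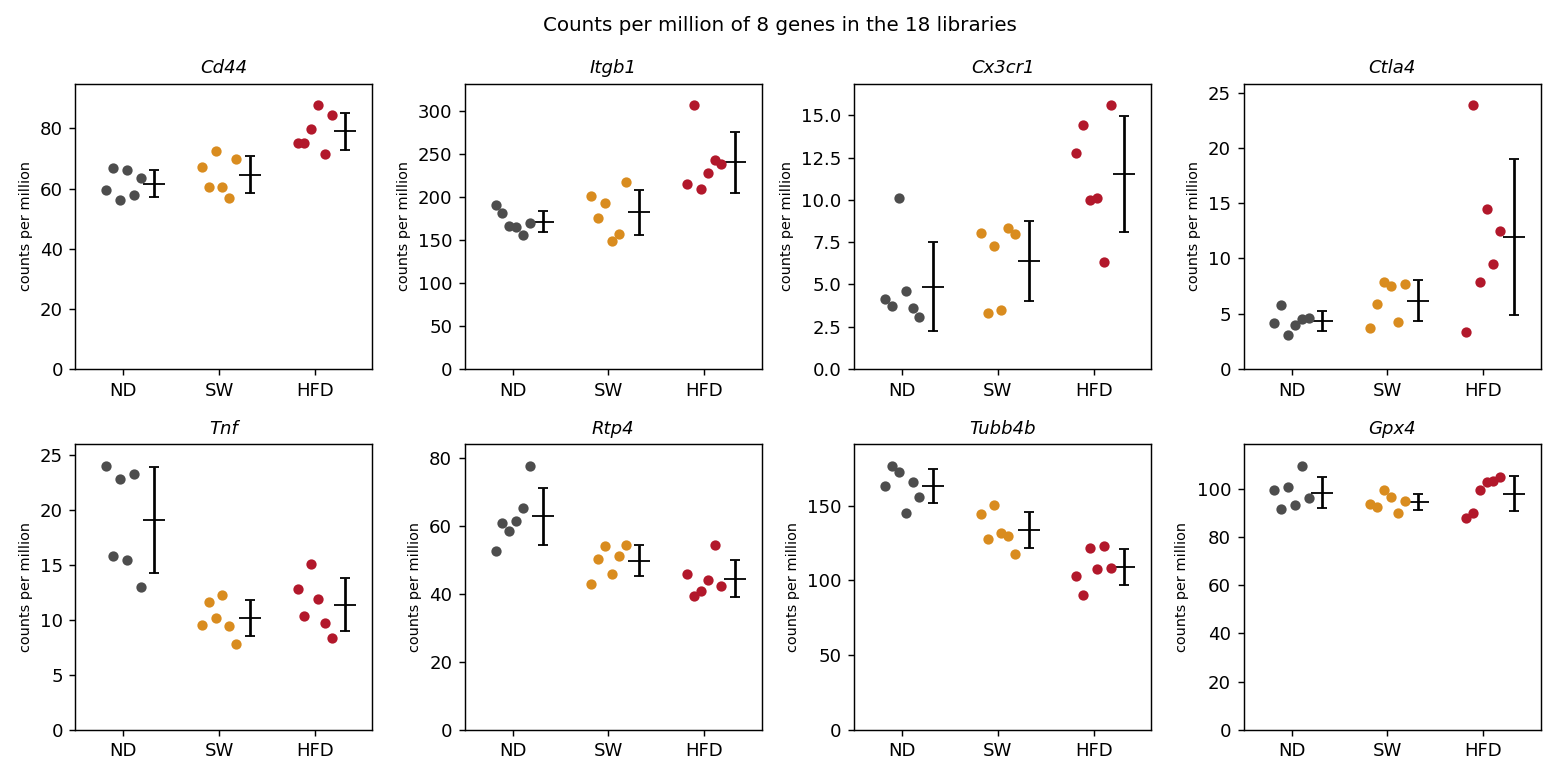
CPM (vertical axes) of 8 genes in each library, by diet, with a point per library and the mean and SD of the 6 libraries beside them. Tnf averaged 19.1 CPM in ND, 10.1 in SW and 11.4 in HFD, and Cd44 averaged 61.6, 64.6 and 79.0.

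**Figure D3:**
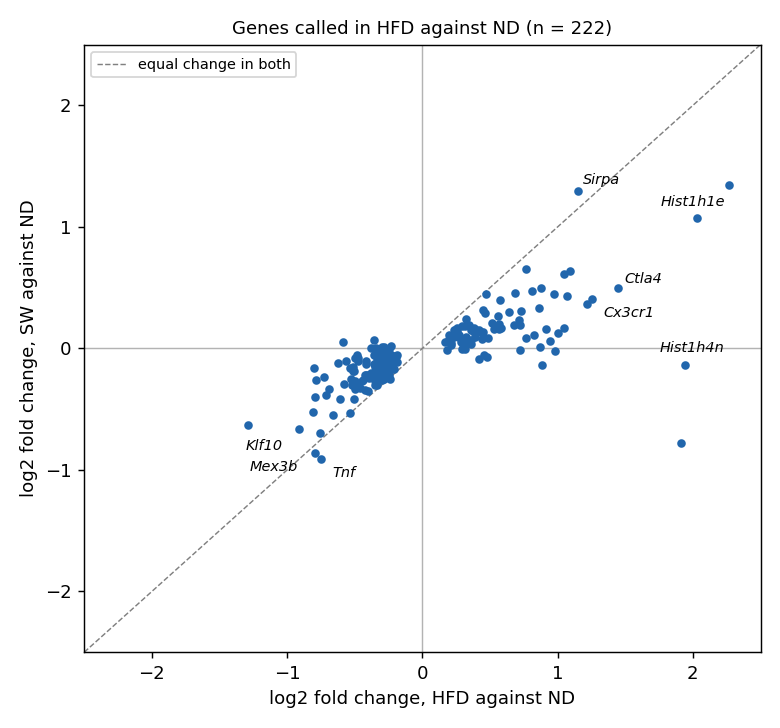
Log2 fold change of SW against ND (vertical axis) against that of HFD against ND (horizontal axis) for the 222 genes called in HFD against ND, 1 point per gene, with a dashed line where both are equal. The signs were the same for 203 of the 222 genes. Simulations without any diet effect gave 200 to 212 of the top 222, so this count does not tell a shared change from shared ND libraries. With ND divided so that none were shared, 173 of the top 222 had the same sign on average (range 136 to 188).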

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

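The tests for natural killer cells, for a larger share of effector cells, for a single ND library and of the splits balanced for replicates 1 and 2 were chosen after the results they measure were seen. The splits of the libraries as a whole, the test without HFD 1 and HFD 4 and the test of the replicate sets were set before theirs.

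Single libraries stood apart from the other 5 of their diet, by a gap over 0.625 of the range (Dixon's test), in 29 of 417 sets of 6 values, where chance gives about 1 in 20, or 20.9. The flags fell on 10 sets of ND, 9 of SW and 10 of HFD, with 4 on HFD 1 and 3 on HFD 4. Levels are log2 CPM, and those of lists are means over members. In ND, the interferon list stood out at 5.89 in ND 6, Cx3cr1 at 3.36, Tcf7 at 10.53 and Elovl1 at 5.94 in ND 3, Hbb-bs at 2.26 in ND 6, Tsc22d3 at 8.14 and Txnip at 9.45 in ND 1, Zfp707 at 4.83 in ND 4 and Polr3f at 5.43 in ND 5. In SW, the iron list stood out at 5.64 in SW 4, the list of fatty acid desaturation and membrane remodelling at 4.71 and the unfolded protein list at 5.82 in SW 3, the heat shock list at 7.12 and Hspa1b at 3.35 in SW 1, Mex3b at 3.12 and Acat2 at 4.23 in SW 6, and Alg2 at 5.18 and Wdfy4 at 5.03 in SW 5. In HFD, the desaturation list stood out at 4.43 and Smpdl3b at 2.07 in HFD 4, Cd36 at 4.05, Cd74 at 9.75, Tsc22d3 at 8.42 and Txnip at 9.36 in HFD 1, Slc4a1 at -2.28 in HFD 5, and Pmaip1 at 5.32 and Bhlhe40 at 3.72 in HFD 2. The gene ID ENSMUSG00000119584, which has no symbol in GENCODE M21, took 0.494% of the counts in ND 1 and 0.978% in HFD 4.

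Chance was unlikely for the 222 genes of HFD against ND: in 1 of 100 splits of the 12 libraries, the real one, were as many genes called, and the highest other split called 2. A share below 1 of 100 cannot be reached with this number of splits. The splits also treat the libraries as independent, and the labels do not say that they came from separate mice. For the 123 genes among the 3 diets chance was also unlikely but not excluded. There 2 of 100 splits, the real one included, called as many, and the highest other called 230. Over all splits it cannot be excluded for the 2 genes of SW against ND, where 5 of 100 splits called as many and the highest other called 450, nor for the 17 genes of SW against HFD, where 5 of 100 did and the highest other called 504. Splits with several times the real count point to a structure of the samples. In the highest for SW against ND and for SW against HFD, all 4 libraries of replicates 1 and 2 were in 1 group, and with these replicates against 3 to 6 as a factor 22 and 116 genes were called. Every diet holds 2 libraries of replicates 1 and 2, and few of the splits balanced in the same way reached the gene counts. The real split alone called as many in 43 for HFD against ND (highest other 0) and in 47 for SW against ND (highest other 0). For SW against HFD 2 of 56 did (highest other 23). This subset of splits was chosen after the results were seen, so it does not exclude chance for the 2 SW comparisons. For the lists passing camera with a preset correlation, chance cannot be excluded in any comparison. The 10 of HFD against ND were reached in 15 of 100 splits (highest other 13), the 7 of SW against ND in 48 (highest other 14) and the 12 of SW against HFD in 13 (highest other 17). Among the balanced splits, 7 of 43, 22 of 47 and 8 of 56 reached these numbers of lists (highest other 11, 14 and 17).

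The effector and memory list was higher in HFD than in ND, at a median of 0.36. The libraries HFD 1 and HFD 4 alone are excluded as the cause, since the median was 0.353 without them (camera adjusted p = 2.58e-18). Natural killer cells carried along in the sort stay open, since the natural killer list had a mean of 0.27 ± 0.13 (SE over libraries, n = 6 per diet; 8 genes, 1 of them also in the effector list) and the effector list one of 0.47 ± 0.07 (36 genes), which cannot be told apart by these errors. A larger share of effector or memory cells among the sorted cells may also account for it and stays open, since the naive list did not fall, with a median of 0.062, but bulk values do not count cells. Markers of other cells were higher in HFD too, with medians of 0.80 for the monocyte, macrophage and neutrophil list (adjusted p = 0.0454 with an estimated correlation) and 1.04 for the 4 plasma cell genes, of which Prdm1 is also in the effector list. Such cells stay open as well, as does an effect of the diet on the genes within each cell. The histone list, fixed for RNA quality, was also higher in HFD (median 0.53, camera adjusted p = 0.00484 with an estimated correlation). Whether RNA quality had a part in the effector rise was not tested.

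The type I interferon list was lower in HFD and in SW than in ND, and both comparisons rest on the same ND libraries. A single ND library is not the whole cause by the bound set for it, since without ND 6, the highest, the median was -0.127 in HFD and -0.097 in SW, with camera calls in both, but leaving it out moved each median by over 1.5 times. Every diet holds equal numbers of libraries of replicates 1 and 2 and of replicates 3 to 6. An even offset between these sets therefore cancels by design and needed no test. Within the respective sets the medians were -0.18 and -0.23 in HFD and -0.14 and -0.15 in SW, so the difference was not confined to 1 set. With an estimated correlation neither list call passed (adjusted p = 0.213 and 0.279), so that a shared swing of the interferon genes between samples, unrelated to diet, stays open, as does an effect of a past or present high fat diet.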

How the results depend on the processing

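The fits with replicates 1 and 2 against 3 to 6 as a factor, with 1 of these sets, without HFD 1 and HFD 4 or with a marker covariate were chosen after the data were seen; all other alternatives were planned. The cause of a moved count was not tested, except that the fits of 1 set of replicates have fewer libraries and the unfiltered fits more genes. For HFD against ND, SW against ND, SW against HFD and the genes changed among the 3 diets, in this order, edgeR called 222, 2, 17 and 123 genes. DESeq2 called 479, 61, 112 and 438, and gave no adjusted p to 267, 1859 and 1 genes in the pairwise comparisons. Limma-voom called 372, 29, 8 and 256. The labels do not say that equal replicate numbers pair the libraries, and the correlations do not settle it. Of 18 same-numbered pairs 12 correlated above 0.1, with a range of -0.0192 to 0.404, and 5 of 18 libraries correlated best with their own number. With the replicate block the counts were 598, 49, 138 and 469. With replicates 1 and 2 against 3 to 6 as a factor they were 535, 22, 116 and 444, and within replicates 1 and 2 alone 5, 0, 2 and 5. With replicates 1 to 3 against 4 to 6 as a factor they were 9, 58 and 248 for the last 3. The erythroid covariate gave 80, 20, 4 and 77, and the dendritic cell covariate 1 for SW against ND and 0 for SW against HFD, where 1383 genes had an unadjusted p under 0.05. Without a filter on low counts 31, 53 and 216 genes were called in the last 3. Fits of only the diets compared called 19 in SW against ND and 0 in SW against HFD. In SW against ND, other size factors and library totals each called 1 and replicates 3 to 6 alone 5; without HFD 1 and HFD 4, 14 were called there and 28 in SW against HFD. On FPKM with 0.1 added, limma called 0 in SW against ND, 0 in SW against HFD and 78 among the 3 diets, with 1 added 0 and 0, and without a filter 41, 0, 1 and 27. Library totals gave 78 higher and 179 lower genes in HFD against ND, beside 91 and 131, and 16 and 8 in SW against HFD, beside 8 and 9. Leaving out 1 library gave 89 to 301, 0 to 16, 0 to 44 and 62 to 220 genes.

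With an estimated correlation 4, 0 and 2 lists passed camera in the 3 pairwise comparisons, in place of 10, 7 and 12. With fry 7 passed in HFD against ND, 0 in SW against ND and 7 in SW against HFD. In replicates 3 to 6 alone 11 passed in SW against ND and 3 in SW against HFD, and in replicates 1 and 2 alone 11 in SW against ND. Leaving out 1 library gave 10 to 14, 4 to 10 and 8 to 16 lists. The covariance of the fold changes, 0.0266, was 0.0138 with ND divided, 0.0431 in replicates 3 to 6, and 0.0249 to 0.0350 without 1 library.

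Depth and spread limit small changes: for HFD against ND, 26% of the smallest simulated changes and 70% of those of 1.5-fold were recovered.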

Other observations

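The glucocorticoid, FOXO and library tests were set before their results were seen, and the genes described here were chosen after their values were seen.

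The 3 smallest p-values of HFD against ND in the edgeR test belonged to Tubb4b, Tuba4a and Rbm12. Tubb4b (ENSMUSG00000036752; 2, 25222160 to 25224702, GRCm38) changed by -0.58 ± 0.07 (SE; edgeR adjusted p = 8.88e-05), from 163 ± 11.6 CPM in ND to 109 ± 12.2 in HFD (SD, n = 6), in 6 of 6 libraries with no overlap. Tuba4a changed by -0.48 ± 0.06 (adjusted p = 0.000125), Tuba1a by -0.39 ± 0.08 and Tuba1b by -0.21 ± 0.05, and Dynll1, a dynein light chain gene, by -0.48 ± 0.10. Rbm12, which encodes an RNA-binding protein, changed by -0.53 ± 0.07 (adjusted p = 0.000125). In the 18 fits without 1 library Tuba1b was called in 10 (adjusted p up to 0.0837) and the other 5 in all. The alpha tubulin genes are alike in sequence, so that reads can be shared among them. In SW against ND, Tubb4b was at -0.29 ± 0.07 (adjusted p = 0.123) and Tuba4a at -0.31 ± 0.06 (adjusted p = 0.0634).

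Tsc22d3, Txnip, Pik3ip1 and Il7r rose in HFD, by 0.88 ± 0.18, 0.73 ± 0.17, 0.26 ± 0.06 and 0.43 ± 0.09 (SE; edgeR), and all are known targets of glucocorticoid or FOXO signalling. In the 18 fits without 1 library Txnip was called in 6 (adjusted p up to 0.0849), Tsc22d3 in 15 (adjusted p up to 0.0544) and the other 2 in all. Stronger glucocorticoid signalling may be proposed as the cause, but 8 tested glucocorticoid targets outside this group (of 11 listed) had a mean of 0.046 ± 0.055 (SE over libraries), below the bound set from the mean of the 4 genes, 0.54 ± 0.14. Of these 8 targets 4 were above 0, with Cxcr4 at 0.54 ± 0.20 and Per1 at 0.25 ± 0.08 (SE of the fit), and Errfi1 was at -0.36 ± 0.10. None was called. Since the targets moved both ways, their mean does not exclude glucocorticoid signalling. For stronger FOXO activity, 7 other FOXO targets, with a mean of -0.090 ± 0.045 and 2 above 0, argue against it. The 4 genes had a mean of 0.66 without HFD 1 and HFD 4. HFD 1 was the lowest HFD library for Tsc22d3, Txnip and Il7r, so that leaving it out could only raise these, and its values exclude it as the source of their rise. HFD 4 alone is excluded as the source, since without it Tsc22d3, Txnip, Pik3ip1 and Il7r were at 0.82, 0.68, 0.26 and 0.43. No other cause was tested.

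HFD 4 had counts for 17570 genes, and the other 17 libraries for 18963 to 20155. PC1 ran from -11.59 to -7.69 in replicates 1 and 2 and from -3.53 to 10.34 in replicates 3 to 6.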
